A study of Homo sapiens with 768 samples.

How the data were processed

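The data are UMI (unique molecular identifier) counts per gene from 768 single cells of H9, an established human embryonic stem cell line, sorted at 1 cell per well into 2 plates of 384 wells. One plate held undifferentiated cells. The other held cells stained with an antibody to APA (aminopeptidase A, gene ENPEP) after 3 days with BMP4 at 50 ng/ml. Per the labels' protocols the libraries were made by SCRB-seq, in which a barcoded primer in each well marks the cell and the molecule, and the 3' end of each transcript is sequenced. Amplified copies of 1 molecule therefore count once.

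The authors deposited 1 table of whole-number UMI counts, not normalized, with 33725 Ensembl gene identifiers and all 768 wells as columns. The aligner STAR and the genome build hg38 (GRCh38) are named in the submitters' processing notes. The version of STAR, the annotation release, the counting tool, the rule for collapsing UMIs, the use of strand and any filter are not given in the sources used here. Reads that match several genes equally well are often dropped or split by such counting, so genes with near-identical copies are treated as uncertain. Reads were not analysed here, nor was the well barcode list.

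Wells were mapped to plates by their labels. The well names give plate positions, and a position that occurs on both plates carries no pairing of cells. Gene symbols came from a table of Ensembl identifiers, which matched 32827 identifiers. The 898 without a symbol held 1.69% of all UMIs and stayed in the totals. Coordinates are those of GENCODE release 29 on GRCh38. No column of the table was left unused.

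A well was kept if it had at least 500 detected genes and if the log10 of its total was no more than 3 scaled median absolute deviations (scale 1.4826) under its plate's median. No upper limit was set. This kept 381 of 384 APA-positive wells and 353 of 384 undifferentiated wells. No doublet caller was run, because wells were filled 1 cell at a time. An alternative left out wells with more than 2 times their plate's median UMIs, which also removes most deep wells. Kept APA-positive wells had a median of 3566 UMIs and kept undifferentiated wells a median of 5910 UMIs.

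Each condition is 1 plate, and the labels name no separate cultures, so each group is 1 sample and plate and condition cannot be told apart. No p-value, standard error or count of changed genes was computed from cells. UMIs were summed over the kept wells of a plate and given as CPM (counts per 1 000 000 UMIs) with exact Poisson intervals. Ratios of CPM, APA-positive over undifferentiated, carry exact conditional binomial intervals, and shares of wells carry exact Clopper-Pearson intervals. Where a share was 0, the limit given is instead 3 wells of the total, and it limits wells with a UMI rather than cells that express the gene. All intervals are at 95% and cover counting error only, not the spread between cultures or between cells. Where a plate held 0 UMIs of a gene, the ratio was taken against a floor of 3 UMIs over the whole plate and is a lower bound.

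For 26 gene lists fixed before the data were examined, the number of measured members (at least 20 UMIs over both plates) with a ratio of at least 2 or at most 0.5 was counted. Members whose ratio is a bound entered the medians at that bound. The percentile of each list's median log2 ratio was taken among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these 2 libraries and not a test. The 26 lists cover the network factors, pluripotency, trophectoderm, differentiated trophoblast and amnion. They also cover BMP, Nodal and Activin, and WNT signalling, and mesoderm, endoderm, neuroectoderm, surface ectoderm, and stroma with endothelium. Further lists hold epithelial junctions, mesenchymal genes, basement membrane and matrix, S phase, G2 and M phase, cholesterol synthesis, glycolysis, and mitochondrially encoded genes. The last lists hold stress and early response, p53 targets, imprinted and placental growth genes, DNA methylation, and MHC class I presentation. Several amnion genes are also expressed by trophoblast, so the lists alone do not tell trophoblast from amnion.

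Genes were named by a rule fixed beforehand. It took the 4 network factors, POU5F1, NANOG, SOX2 and ENPEP. It also took the 12 highest and 12 lowest ratios among genes of at least 50 CPM in the higher plate, ranked by the interval bound nearest 1, without mitochondrial and ribosomal protein genes and pseudogenes. From each list it took the 2 members with the largest and the 2 with the highest values, and 4 of each in the pluripotency and trophectoderm lists. Last, it took the 10 genes with the highest Fano factor (variance over mean) per plate and the 10 leading genes of each cluster. Other genes named in the text were chosen after their values were seen.

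To compare shares of wells across depths, each well was thinned to 1500 UMIs, the 10th percentile of the kept wells rounded down, and shallower wells were left out. Fano factors used the same thinned counts for genes with a mean of at least 0.5 UMI. Clusters were made by the Leiden method at resolution 0.5 on log-normalised counts of 1000 variable genes, 20 principal components and 15 neighbours. A cluster was given a cell-type name only from marker genes fixed beforehand, with at least 3 detected and with its leading genes not against the name. No name was given where none of the markers was among the leading genes.

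Alternatives fixed before the data were examined were the mean of each well's own CPM, a TMM factor from edgeR, thinning before summing, and mitochondrial genes left out of totals. Others were no cell filter, a stricter filter, no wells of high UMI count, each part of the plate by columns and by rows, and no wells that clustered with the other plate. The limits of 1 or 100 UMIs for measured members, size rules of 1.5-fold and 3-fold, other thinning depths and other cluster settings were also tried. Settings chosen after seeing the data left out wells P23 and P24 of both plates, or kept only deep wells. Deep wells had at least 10000 UMIs and were not P23 or P24 (79 APA-positive and 103 undifferentiated wells). The strictest setting also left out APA-positive wells opposite, that is at the same plate position as, an undifferentiated well of at least 10000 UMIs. It is called the deep-well subset and holds 49 APA-positive and 103 undifferentiated wells. Marker lists of liver, red blood cells, plasma cells and melanocytes were also written after the leading genes of wells P23 and P24 had been seen.

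The ratio step was tested on simulated data drawn from the real plate totals for 17570 genes, with 50 genes at each simulated fold. At 4-fold, 50 were called at least 2-fold apart, and 49 at 2.5-fold. On the lower side 50 were called at a ratio of 0.25 and 49 at 0.4. Of 17370 unchanged genes, 1.63% passed the 2-fold rule, and 0.00891% of the 11226 with at least 100 UMIs. The intervals held the true ratio of 95.7% of unchanged genes. The test for transcripts shared between positions gave ratios of 0.998, 1.10 and 1.26 on simulated data with 0%, 2% and 10% carry-over.

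Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9, and edgeR 4.0.16 for the TMM factor.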

Results

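Single-cell transcriptomes were compared between undifferentiated H9 human embryonic stem cells and cells of the same line sorted for surface APA after 3 days of BMP4. BMP4 is a growth factor used to drive such cultures towards trophoblast, the outer cell lineage of the placenta. APA is aminopeptidase A, a membrane protease encoded by ENPEP, and here the sorting antigen for trophoblast progenitors. The series title concerns a network of GATA2, GATA3, TFAP2A and TFAP2C that links trophectoderm differentiation to the shutdown of pluripotency. The 2 plates permit 1 comparison, of the levels of these factors, of pluripotency genes and of other gene groups between the conditions. No well had a factor removed or added, as far as the labels say.

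Of 384 wells per plate, all but 3 APA-positive and all but 31 undifferentiated wells were kept. APA-positive wells held a median of 3566 UMIs (lowest 694) and 2051 detected genes, and 5043807 UMIs in total. Undifferentiated wells held a median of 5910 UMIs (lowest 659) and 3004 detected genes, and 6014962 UMIs in total. Mitochondrial genes took a median of 15% and 15.2% of UMIs. Wells P23 and P24 alone held 29.6% of the kept UMIs of the APA-positive plate and 18.1% of those of the undifferentiated plate. Both plates also carried transcripts of liver, red blood cell, plasma cell and melanocyte marker genes, which took their highest share of UMIs in these 4 wells. Ratios are therefore given over all kept wells and, for genes named by the rule whose ratio moved by more than 1.5 times, also in the deep-well subset, chosen after seeing the data, which has 49 APA-positive wells. There were no replicate plates, so every interval covers counting error only.

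**Figure D1:**
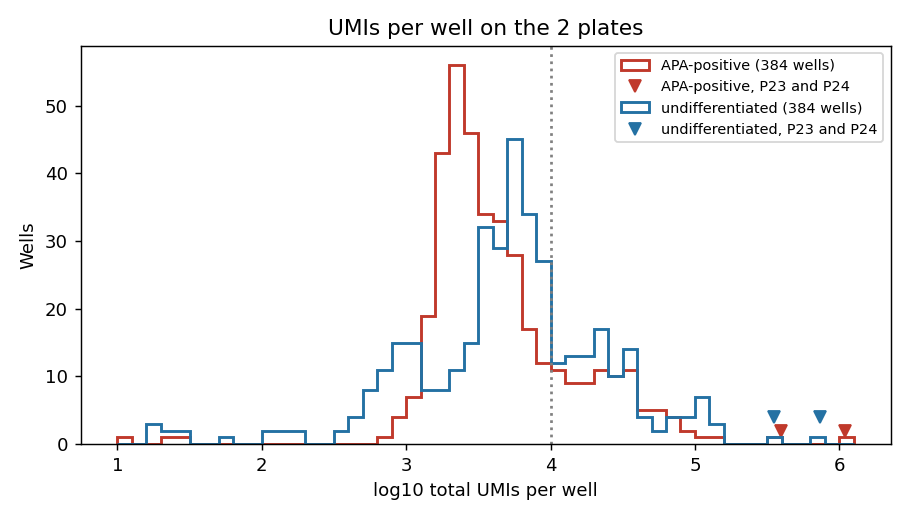
Total UMIs per well on a log axis for the 384 wells of each plate, with wells P23 and P24 marked and a dotted line at 10000 UMIs. Wells P23 and P24 lie above all other wells of both plates and each hold at least 353462 UMIs.

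ENPEP, the gene of the sorting antigen, checked the labels. It stood at 68.2 CPM on the APA-positive plate and 0.998 CPM on the undifferentiated plate (6 UMIs), a ratio of 68.4 (31.1 to 187.6), and 110.6 in the deep-well subset (42.5 to 410). As the basis of the sort it is not a finding between the plates. ENPEP lies on chromosome 4 from 110365733 to 110565285, plus strand.

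All 4 factors of the network were higher in APA-positive cells. GATA2, a zinc-finger factor of trophoblast and blood, was 20.3-fold higher (15.5 to 27.2), at 185.97 against 9.14 CPM. TFAP2A, a factor of trophoblast and surface ectoderm, was 7.34-fold higher (6.04 to 8.98), at 145.1 against 19.8 CPM. GATA3, the related zinc-finger factor, was the most abundant of them at 473 against 85.8 CPM, 5.51-fold higher (5.01 to 6.08). TFAP2C, also present in naive pluripotent cells, was 4.08-fold higher (3.35 to 5.00), at 88.2 against 21.6 CPM. The list's median log2 ratio of 2.67 lay at percentile 100 of random lists matched on expression. The deep-well subset gave larger differences for all 4, at 84.1-fold for GATA2 (49.6 to 154.9), 25.7-fold for TFAP2A (17.8 to 38.5), 15.2-fold for GATA3 (12.9 to 18.2) and 5.55-fold for TFAP2C (4.29 to 7.23), and the list's median was 4.31. In the annotation GATA2 lies on chromosome 3 from 128479427 to 128493185 (minus strand) and GATA3 on chromosome 10 from 8045378 to 8075203 (plus strand). TFAP2A lies on chromosome 6 from 10393186 to 10419659 (minus strand) and TFAP2C on chromosome 20 from 56629302 to 56639283 (plus strand).

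Pluripotency genes were lower in APA-positive cells, with 19 of 24 list members at least 2-fold lower, 1 at least 2-fold higher and 4 between. SOX2, a core factor that POU5F1 binds with, was 4.72-fold lower (4.25 to 5.26), at 81.3 against 384 CPM. NANOG was 6.29-fold lower (4.34 to 9.40), at 6.34 against 39.9 CPM, and POU5F1 was 6.48-fold lower (4.14 to 10.6), at 4.36 against 28.3 CPM. TDGF1, the Nodal co-receptor CRIPTO, was 8.59-fold lower (7.37 to 10.1). PRDM14 and FOXD3, transcription factors of primed pluripotency, were 9.54-fold (4.64 to 22.8) and 8.15-fold (3.75 to 21) lower. UTF1, a chromatin-bound factor, had 1 UMI against 19, 15.9-fold lower (2.53 to 662). DPPA4 and the long noncoding RNA ESRG, both abundant, were 4.12-fold and 3.95-fold lower. The 4 members within 2-fold were L1TD1 at 613 against 597 CPM, a ratio of 1.03 (0.979 to 1.08), LIN28A, 1.27-fold lower (1.2 to 1.34), and, named after their values were seen, LIN28B at a ratio of 0.795 (0.710 to 0.888) and SALL4 at 0.650 (0.584 to 0.724). The member at least 2-fold higher was ZFP42, also known as REX1, at a ratio of 2.13 (1.89 to 2.41), named after its value was seen. The list's median log2 ratio was −2.02, at percentile 0 of random lists.

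Several of these differences were larger in the deep-well subset, where SOX2 was 10.2-fold lower (8.08 to 13), NANOG 27.2-fold lower on 3 APA-positive UMIs (9.17 to 133.1) and TDGF1 102.6-fold lower (47 to 280). PRDM14 was then 30.3-fold lower on 1 APA-positive UMI (5.27 to 1215), and UTF1 had no APA-positive UMI against 14, at least 1.99-fold lower. POU5F1 was then 12.2-fold lower (5.12 to 38.2), and the list's median log2 ratio was −3.23 with 18 of 23 members at least 2-fold lower. POU5F1 had few UMIs, while its near-identical retrogene POU5F1B was counted at 10.7 against 69 CPM, 6.44-fold lower (4.84 to 8.72). TDGF1P3, a processed copy of TDGF1, was 11.8-fold lower (9.22 to 15.3; log2 ratio −6.89 in the deep-well subset), and TERF1P4 and TERF1P5, copies of the telomere protein gene TERF1, were 6.06-fold and 6.67-fold lower. Reads of these genes may not have been told apart from those of their copies, so their levels are uncertain. The annotation places POU5F1 on chromosome 6 from 31164337 to 31180731 (minus strand), NANOG on chromosome 12 from 7787794 to 7799141 (plus strand) and SOX2 on chromosome 3 from 181711924 to 181714436 (plus strand).

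Trophectoderm and trophoblast progenitor genes were higher, with 18 of 22 measured list members at least 2-fold higher, 2 at least 2-fold lower and a median log2 ratio of 3.29 (percentile 100). The list includes ENPEP, the gene of the sorting antigen, which is among the 18 and was fixed by the sort. The bHLH factor HAND1 had 131.2 CPM against 0, at least 263.2-fold higher against a floor of 3 UMIs over the plate. The homeobox factor MSX2 was 38.7-fold higher (25.6 to 61.4), and the hypoxia-inducible factor EPAS1, which trophoblast expresses strongly, was 37.9-fold higher (32.2 to 45) at 920 against 24.3 CPM. VGLL1, a TEAD cofactor of trophoblast, was 82.3-fold higher (14.3 to 3297) on 69 UMIs against 1. The epithelial keratins KRT19, KRT8 and KRT18 were 8.39-fold (7.77 to 9.08), 3.97-fold (3.68 to 4.28) and 2.29-fold (2.15 to 2.43) higher. The 2 lower members, named after their values were seen, were the laminin receptor subunit ITGA6 at a ratio of 0.289 (0.260 to 0.320) and the WNT antagonist FRZB at 0.419 (0.204 to 0.807). CDX2 and ELF5, factors of trophoblast stem cells, had under 20 UMIs over both plates and were not measured. Of the 22 measured in the deep-well subset 19 were at least 2-fold higher and the same 2 members lower, with a median log2 ratio of 4.23. ITGA6 and FRZB then had log2 ratios of −2.67 and −2.10. EPAS1 was then 107.6-fold higher (82 to 144.1) and MSX2 105.6-fold higher (55.1 to 232.5). KRT19 and KRT8 were then 14.5-fold (13.1 to 16.2) and 6.97-fold (6.21 to 7.85) higher, and VGLL1 at least 26.5-fold higher on 0 undifferentiated UMIs.

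Of the differentiated trophoblast markers 13 of 26 were measured, and 9 of these were at least 2-fold higher and none lower, with a median log2 ratio of 2.04 (percentile 100). GCM1, the factor that starts syncytiotrophoblast formation, was at least 29.8-fold higher (75 UMIs against 0). ERVFRD-1, which encodes the fusion protein syncytin-2, was at least 13.9-fold higher (35 UMIs against 0). The extravillous markers ITGA1 and MMP2 stayed within 2-fold, ITGA1 at 1.5-fold lower (1.21 to 1.86) and MMP2 at 1.28-fold higher (1.02 to 1.61). Of 9 measured in the deep-well subset 6 were higher and 1 lower, with a median of 3.05, and ITGA1 was 2.32-fold lower (1.4803 to 3.80).

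Amnion-associated genes were also higher, with 11 of 13 measured members at least 2-fold higher, none lower and a median log2 ratio of 3.21 (percentile 100). ISL1, a homeobox factor of amnion and early mesoderm, was at least 58.8-fold higher (0 undifferentiated UMIs). VTCN1, an inhibitory ligand of T cells found on amnion and trophoblast, was 71.6-fold higher (34.4 to 179.1). IGFBP3, which binds insulin-like growth factors, was 4.33-fold higher (3.99 to 4.69), and the nuclear receptor NR2F2 was 4.08-fold higher (3.38 to 4.94). Within the deep-well subset IGFBP3 and NR2F2 were 11.5-fold (9.93 to 13.3) and 13.6-fold (9.66 to 19.7) higher, and VTCN1 139.6-fold on 3 undifferentiated UMIs (47.02 to 683), with 11 of 12 members higher and a median of 4.21. Trophectoderm and amnion lists thus stood higher in the same plate total, and several amnion genes are also expressed by trophoblast. The list counts therefore do not set trophoblast apart from amnion.

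The 12 genes with the highest ratios by the naming rule included several outside the lists. FOXI1, the forkhead factor of ionocytes and other acid-secreting cells, was 326.8-fold higher (58.2 to 12953) with 1 undifferentiated UMI. ATP6V1C2, a subunit of the vacuolar proton pump, was 85.3-fold higher (32.9 to 315.1). The acid phosphatase ACP3 was 243.3-fold higher (82.9 to 1183), on 3 undifferentiated UMIs. HAPLN1, which links hyaluronan to proteoglycans, was 120-fold higher (60.5 to 278.6). LRP2, the endocytic receptor megalin, was 86-fold higher (49 to 167.02), and the matrix glycoprotein SPARCL1 was 44-fold higher (23.7 to 92.5). On the lower side stood CUZD1, which encodes a secretory-granule protein, at 14.5-fold lower (10.4 to 20.9). GPR176, an orphan receptor, was 11.2-fold lower (7.95 to 16.3), LRAT, the enzyme that esterifies retinol, 9.20-fold lower (7.16 to 12), and CNMD, an inhibitor of blood vessel growth, 8.68-fold lower (6.69 to 11.4). In the deep-well subset HAPLN1 was 205.9-fold higher (87.6 to 637), ATP6V1C2 369.7-fold higher on 1 undifferentiated UMI (65.4 to 14696) and FOXI1 at least 146.7-fold higher on 0. CUZD1 was 191.4-fold lower (34.2 to 7578) and GPR176 151.3-fold lower (26.98 to 5992), each on 1 APA-positive UMI. LRAT was 80.3-fold (27.3 to 391) and CNMD 41.3-fold (17.6 to 127.7) lower.

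Noncoding transcripts made up 7 of the 12 genes with the lowest ratios. MIR302CHG, the host transcript of a microRNA cluster of pluripotent cells, was 9.03-fold lower (8.19 to 9.97) at 88 against 795 CPM, and 65.3-fold lower in the deep-well subset (43.8 to 102.03). LINC00458 was 7.47-fold lower (6.71 to 8.32), LINC00678 11.1-fold lower (8.40 to 15.1) and MIAT 7.94-fold lower (6.40 to 9.95). LNCPRESS2 was 10-fold lower (6.93 to 14.9) and MGC32805 11.6-fold lower (8.10 to 17.2). FOXD3-AS1 was 11.7-fold lower (8.53 to 16.4), and since the use of strand is not given its reads may include those of overlapping genes. Ratios in the deep-well subset were 20.6-fold lower for LINC00458 (15.7 to 27.6), 110.5-fold for LINC00678 (30.4 to 915), 26.8-fold for MIAT (14.5 to 56.1), 56.8-fold for LNCPRESS2 (15.6 to 472) and 103.8-fold for FOXD3-AS1 (28.6 to 860). LINC00678, LNCPRESS2 and FOXD3-AS1 had 2 APA-positive UMIs each there.

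**Figure D2:**
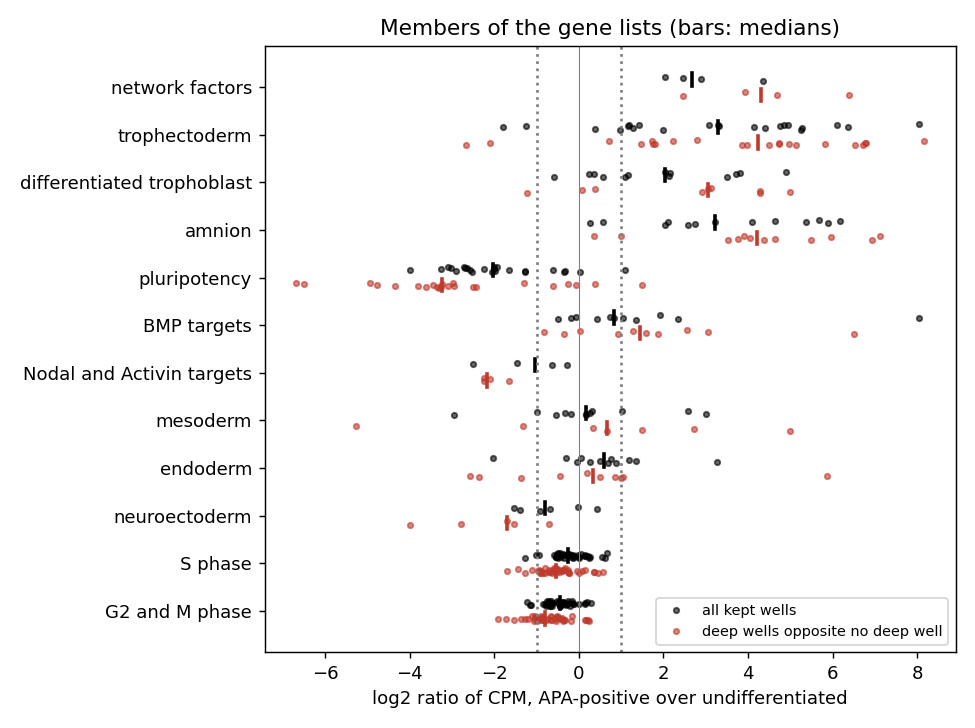
Log2 ratio of CPM, APA-positive over undifferentiated, for each measured member of some of the 26 gene lists (points), with the list median as a bar. Values are given over all kept wells and in the deep-well subset. Drawn are network factors, trophectoderm, differentiated trophoblast, amnion, pluripotency, BMP targets, and Nodal and Activin targets. Also drawn are mesoderm, endoderm, neuroectoderm, S phase, and G2 and M phase, while the other lists are not. Medians over all kept wells run from −2.02 for the pluripotency list to 3.29 for the trophectoderm list.

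Among targets of the signalling pathways, 5 of 11 measured BMP targets were at least 2-fold higher and none lower, with a median log2 ratio of 0.82 (percentile 99.9). They included ID2 at 5.11-fold (4.36 to 6.02) and ID1 at 2.54-fold (2.28 to 2.83), both inhibitors of bHLH factors. The BMP antagonist GREM2 was 261.2-fold higher (46.4 to 10362) with 1 undifferentiated UMI. Of the Nodal and Activin targets only 4 of 10 were measured, and 2 were at least 2-fold lower, with a median log2 ratio of −1.05 (percentile 0.4). These were FOXH1, the SMAD partner of Nodal signalling, at 5.67-fold lower (4.07 to 8.07), and the SMAD corepressor SKIL at 2.76-fold lower (2.48 to 3.08). In the deep-well subset all 4 were at least 2-fold lower, SKIL by 4.25-fold (3.48 to 5.23). There 6 of 10 BMP targets were higher and none lower, with a median of 1.44, ID2 at 8.26-fold higher (6.57 to 10.5) and GREM2 at least 91.3-fold on 0 undifferentiated UMIs. WNT targets went both ways, with 2 of 11 higher, 1 lower and a median log2 ratio of 0.32 (percentile 88.3), and 1 of 6 higher and 1 lower in the deep-well subset. The ubiquitin ligase RNF43 and the antagonist DKK1 were 3.36-fold (2.35 to 4.87) and 2.76-fold (1.65 to 4.79) higher, while the factor TCF7 was 1.32-fold higher (1.10 to 1.6).

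Of 12 measured mesoderm genes 3 were at least 2-fold higher and 1 lower, with a median log2 ratio of 0.17 (percentile 78). TBX3, a T-box factor that trophoblast also uses, was 8.06-fold higher (6.34 to 10.4), and the receptor KDR, present in undifferentiated cells at 76.5 CPM, was 7.71-fold lower (5.75 to 10.5). TBX3 was 31.7-fold higher (19.7 to 54.4) and KDR 38.2-fold lower (14.8 to 141.1) in the deep-well subset, where 3 of 7 mesoderm genes were higher and 2 lower, with a median of 0.67. Of 12 endoderm genes 3 were higher and 1 lower, with a median log2 ratio of 0.59 (percentile 99.5). GATA6 was 9.54-fold higher (4.08 to 27.3) on 48 UMIs against 6, and FOXA3 4.11-fold lower (2.52 to 7.02). GATA6 was 58.5-fold higher in the deep-well subset, on 1 undifferentiated UMI (9.58 to 2402). The plasma proteins APOA2 and AFP, 1.83-fold (1.69 to 1.99) and 1.41-fold (1.27 to 1.57) higher over all kept wells, belong to the liver transcripts that were highest in wells P23 and P24. In the deep-well subset AFP was 1.35-fold lower (1.01 to 1.83), and 2 endoderm members were higher and 3 lower of 10, with a median of 0.35. Neuroectoderm markers were lower in 2 of 6 and higher in none, with a median log2 ratio of −0.80 (percentile 2.24). SOX3 was 2.88-fold lower (1.56 to 5.65), and NES, an intermediate filament of neural progenitors, 2.60-fold lower (2.31 to 2.94). SOX10 was at 1.36-fold higher (0.886 to 2.08). The deep-well subset had 4 of 5 neuroectoderm markers at least 2-fold lower and none higher, with a median of −1.69, SOX3 15.8-fold lower on 1 APA-positive UMI (2.67 to 641) and SOX10 1.62-fold lower (0.586 to 5.56).

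Surface ectoderm and epithelial genes were higher in 5 of 8 measured members and lower in none, with a median log2 ratio of 1.2 (percentile 100.0). DSP, the desmosome protein desmoplakin, was 4.82-fold higher (4.475 to 5.21), PERP, another desmosome gene, 2.20-fold (1.97 to 2.46) and the factor GRHL3 3.73-fold (1.63 to 9.56). KRT5 and KRT14, keratins of basal skin cells, had under 20 UMIs. Of 11 epithelial junction genes only the tight junction gene CLDN4 was at least 2-fold higher, at 5.38-fold (4.46 to 6.53), with a list median of 0.36 (percentile 97.9). CDH1, the epithelial cadherin, was 1.63-fold higher (1.5 to 1.77). The deep-well subset had 4 of the 11 higher, with a median of 0.68, CLDN4 at 10.2-fold (7.94 to 13.4), CLDN7 at 2.63-fold (2.0 to 3.45) and CDH1 at 2.15-fold (1.94 to 2.39). DSP was then 7.275-fold higher (6.56 to 8.08), and 5 of 6 surface ectoderm genes were higher and none lower. EPCAM was 1.29-fold higher (1.19 to 1.40) over all kept wells.

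Of 10 mesenchymal genes none was at least 2-fold higher and 1 lower, with a median log2 ratio of 0.21 (percentile 90.5). That gene was CDH2, the neural cadherin also made by stem cells, at 2.11-fold lower (1.72 to 2.59) and 10-fold lower in the deep-well subset (5.18 to 22.2), where 1 of the 10 was higher and 2 lower, with a median of −0.08. TPM1 and FN1 were 1.96-fold (1.86 to 2.08) and 1.56-fold (1.477 to 1.64) higher. Basement membrane and matrix genes were higher in 3 of 11 and lower in 1, with a median of 0.19 (percentile 89.3). The laminin chains LAMA1 and LAMB1 were 3.90-fold (3.38 to 4.52) and 3.26-fold (2.95 to 3.61) higher, and LAMC1 1.14-fold higher (1.05 to 1.25). In the deep-well subset 3 of the 11 were higher and 5 lower, with a median of 0.47 and LAMB1 at 5.58-fold higher (4.82 to 6.46). Stroma and endothelium markers were higher in 1 of 8 and lower in 1, with a median of 0.51 (percentile 97.7). POSTN was 2.67-fold higher (1.84 to 3.94) and TAGLN 2.01-fold lower (1.41 to 2.92). The collagens COL1A2 and COL1A1 were 1.65-fold higher (1.51 to 1.79) and 1.62-fold lower (1.41 to 1.88). Restricted to the deep-well subset POSTN was 6.35-fold higher (3.36 to 12.7), TAGLN 4.88-fold lower (2.26 to 12.5) and COL1A1 3.42-fold lower (2.53 to 4.72). Of 5 members measured there 2 were higher and 2 lower, with a median of −0.02.

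Of 44 G2 and M phase genes 3 were at least 2-fold lower and none higher, with a median log2 ratio of −0.44 (percentile 0). Of 40 S phase genes 2 were at least 2-fold lower and none higher, with a median of −0.25 (percentile 0.11). The spindle checkpoint kinase BUB1 was 2.32-fold lower (2.06 to 2.62), the spindle protein DLGAP5 2.24-fold (2.03 to 2.47) and the chromatin remodeller HELLS 2.42-fold (2.27 to 2.58). CENPF and TOP2A were 1.61-fold (1.54 to 1.68) and 1.33-fold (1.27 to 1.39) lower, NASP 1.46-fold (1.39 to 1.54) and DSCC1 2.01-fold (1.61 to 2.53). The deep-well subset had 11 of the 44 G2 and M phase genes and 4 of the 40 S phase genes at least 2-fold lower. Their medians were then −0.80 and −0.54, and BUB1 was 3.73-fold lower (2.97 to 4.74).

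None of 21 cholesterol synthesis genes was 2-fold apart, with a median log2 ratio of −0.22 (percentile 3.26), and HMGCS1, an early enzyme of the pathway, was 1.95-fold lower (1.77 to 2.15). FDFT1 and DHCR24 were 1.41-fold and 1.42-fold lower, and MVK 1.51-fold higher (1.06 to 2.14). In the deep-well subset 2 of the 21 were at least 2-fold lower, with a median of −0.44. Of 20 glycolysis genes 4 were at least 2-fold higher and none lower, with a median of 0.09 (percentile 88.9). The glucose transporters SLC2A1 and SLC2A3 were 3.34-fold (3.02 to 3.70) and 2.64-fold (2.48 to 2.82) higher, while GAPDH and ENO1 were at 1.10-fold and 1.25-fold. Of the 20 genes 4 were higher and 4 lower in the deep-well subset, with a median of −0.36 and SLC2A1 at 5.17-fold higher (4.50 to 5.95). None of 13 mitochondrially encoded genes was 2-fold apart, with a median of −0.05 (percentile 42.6) and MT-CO1 at a ratio of 1.01, MT-CO2 at 1.03, MT-ND5 at 1.19 and MT-CO3 1.24-fold lower, and none was in the deep-well subset either. None of 13 stress and early response genes was 2-fold apart, with a median of 0.36 (percentile 98.9). FOS and FOSB were 1.70-fold (1.44 to 2.02) and 1.75-fold (1.15 to 2.66) higher, HSPH1 1.35-fold higher and ATF4 1.28-fold lower. The deep-well subset had 2 of the 13 higher and 2 lower, with a median of 0.15. Of 12 p53 targets 2 were at least 2-fold lower, with a median of 0.13 (percentile 74.1). They were PMAIP1, which encodes the apoptosis promoter NOXA, at 4.13-fold lower (3.56 to 4.80), and RRM2B at 2.41-fold lower (2.03 to 2.88). PMAIP1 was 13.1-fold lower (8.74 to 20.6) in the deep-well subset, where 2 of 11 were lower and none higher, with a median of −0.19. MDM2 was 1.39-fold higher (1.24 to 1.57).

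Imprinted and placental growth genes were higher in 5 of 12 measured members and lower in 1, with a median log2 ratio of 0.94 (percentile 100). The noncoding RNA H19 was 107.9-fold higher (54.5 to 250.9), the cell cycle inhibitor CDKN1C 17.1-fold (12.8 to 23.3) and the retrotransposon-derived gene PEG10, needed for placental growth, 7.02-fold (6.57 to 7.52) at 1156 against 164.6 CPM. SNRPN was 2.96-fold lower (2.66 to 3.31). H19 in the deep-well subset was 589-fold higher (162.1 to 4873) on 2 undifferentiated UMIs, CDKN1C 34.7-fold (23.8 to 52.4) and PEG10 14.1-fold (12.8 to 15.5), while the list's median was 0.23 with 5 of 11 higher and 1 lower. Of 9 DNA methylation genes 2 were at least 2-fold higher and 1 lower, with a median of −0.01 (percentile 53.3). The demethylase TET2 was 5.66-fold higher (4.86 to 6.63), and DNMT3L, a cofactor of methylation in germ cells and trophoblast, at least 7.95-fold higher (20 UMIs against 0). Without P23 and P24 DNMT3L fell under the limit of 20 UMIs, at a ratio of at least 8.78, and 1 of 7 measured members was higher and none lower. TET2 was 8.60-fold higher (7.01 to 10.6) in the deep-well subset, also with 1 of 7 higher and none lower. TET1 was 1.29-fold higher, and DNMT1 differed by less than its counting error at 191.9 against 193.02 CPM. Of 7 measured MHC class I genes 1 was higher and 1 lower, with a median of 0.23 (percentile 81). HLA-A was 2.18-fold lower (1.72 to 2.78) and HLA-C 1.40-fold lower (1.2 to 1.64). HLA-B was 2.07-fold higher (1.21 to 3.63) on 40 UMIs against 23 over all kept wells, but was 2.56-fold lower (0.311 to 117.9) on 1 UMI against 6 in the deep-well subset. B2M was 1.17-fold higher (1.10 to 1.25). In the subset HLA-A was 5.41-fold lower (3.20 to 9.86) and B2M 1.33-fold lower (1.15 to 1.54), and 2 of 4 measured members were lower and none higher, with a median of −0.78.

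Detection in single wells followed these levels. Wells were thinned to 1500 UMIs, and 23 APA-positive and 44 undifferentiated wells that were shallower were left out. GATA3 was detected in 55.9% of APA-positive wells (50.6 to 61.1) and 14.2% of undifferentiated wells (10.5 to 18.6), and GATA2 in 25.7% (21.2 to 30.6) and 0.647% (0.0785 to 2.32). TFAP2A was detected in 19.8% and 3.88%, and TFAP2C in 14% and 2.91%. SOX2 went the other way, at 14% (10.5 to 18) against 50.5% (44.8 to 56.2), as did TDGF1 at 4.47% against 41.1%, NANOG at 1.40% against 6.15% and POU5F1 at 0.838% against 3.56%. ENPEP was detected in 10.9% of APA-positive wells, and in no undifferentiated well, which allows a share of up to 0.971%. ALB, a liver gene that neither state should express, was detected in 29.3% and 29.4% of wells, so shares of this size need not be expression by the cell. Without thinning, shares rose with depth, to 52.8% against 6.80% for GATA2, 82.7% against 44.2% for GATA3, 44.6% against 14.2% for TFAP2A and 41.5% against 20.7% for TFAP2C. The unthinned shares were 35.2% against 79.6% for SOX2, 3.94% against 26.6% for NANOG and 5.25% against 24.9% for POU5F1.

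In the deep-well subset thinned to 10000 UMIs, GATA3 was detected in all 49 APA-positive wells and in 44.7% of undifferentiated wells (34.9 to 54.8). The shares were 77.6% (63.4 to 88.2) against 3.88% for GATA2, 73.5% against 11.7% for TFAP2A and 65.3% against 17.5% for TFAP2C. HAND1 was detected in 73.5% of APA-positive wells and in no undifferentiated well, which allows up to 2.91%. SOX2 was detected in 20.4% (10.2 to 34.3) against 96.1% (90.4 to 98.9), TDGF1 in 2.04% against 99%, and NANOG in 0 of 49 (up to 6.12%) against 35%. ALB was again detected on both plates, in 55.1% and 69.9% of wells. Of the 49 APA-positive wells, 7 held UMIs of 2 of the 4 network factors, 27 of 3 and 15 of all 4. Of the undifferentiated wells in this subset 40 held none, 48 held 1, 13 held 2 and 2 held 3. As GATA3 was found in every APA-positive well of this subset, its pairs could not be compared with chance. The other pairs were found together in 25 wells (GATA2 and TFAP2A), 23 (GATA2 and TFAP2C) and 24 (TFAP2A and TFAP2C), where the product of their shares gives 27.9, 24.8 and 23.5. With wells thinned to 1500 UMIs, GATA2 and GATA3 were found together in 45 APA-positive wells against a product of 51.4, and TFAP2A and TFAP2C in 15 against 9.92. Remaining pairs stood at 18 against 18.2 (GATA2 and TFAP2A), 12 against 12.8 (GATA2 and TFAP2C), 34 against 39.7 (GATA3 and TFAP2A) and 28 against 27.9 (GATA3 and TFAP2C). At 750 UMIs TFAP2A and TFAP2C were found together in 2 wells against 1.69.

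**Figure D3:**
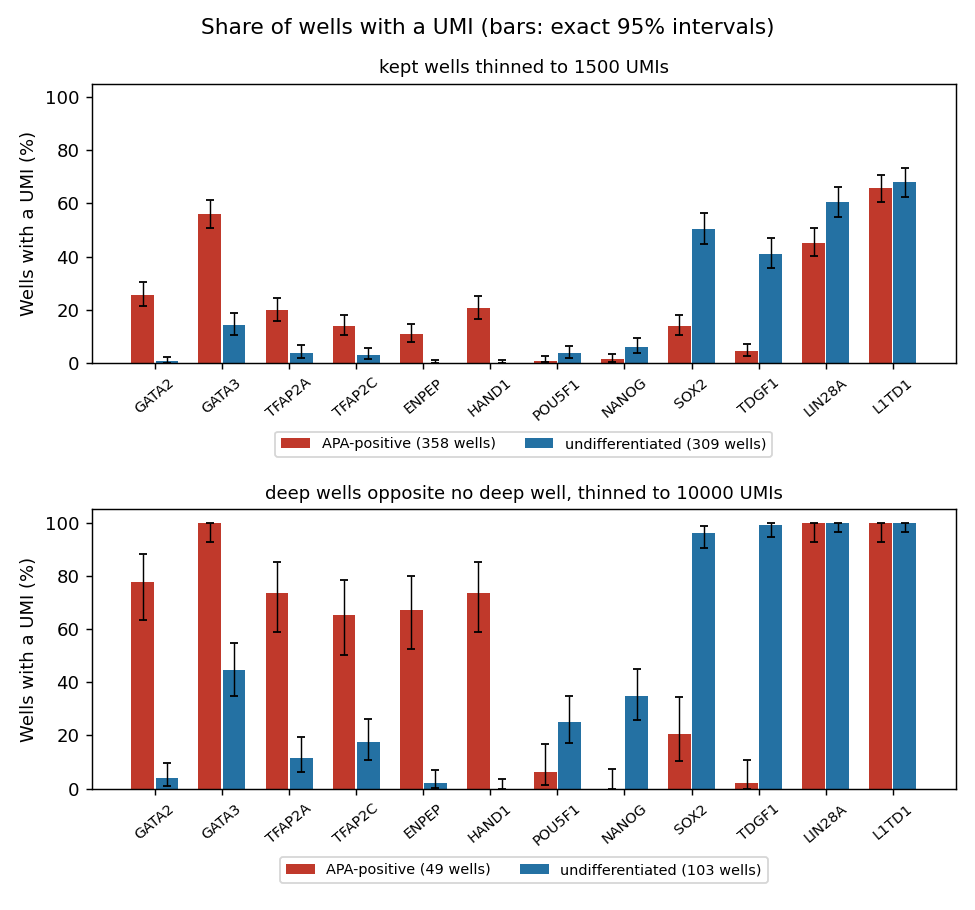
Share of wells with at least 1 UMI of 12 genes, in percent with exact 95% intervals, for wells thinned to 1500 UMIs (upper panel) and for the deep-well subset thinned to 10000 UMIs (lower panel). The 4 network factors, ENPEP and HAND1 are detected in more APA-positive wells, and SOX2, TDGF1, NANOG and POU5F1 in more undifferentiated wells, while L1TD1 and LIN28A are detected in all wells of the deep-well subset.

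Clustering of the kept wells of both plates gave 4 clusters, each held mostly by 1 plate, so that cluster and plate could not be told apart. A cluster of 63 wells, all APA-positive, with a median of 25983 UMIs, had H19, CDKN1C, HAND1, FOXI1, CEBPA, KRT7, CTSV, MSX2, LRP2 and DIO3 as leading genes. With 10 trophoblast markers detected and 2 of them among the leading genes it was called trophoblast-like. As 8 pluripotent and 6 amnion markers were also detected in it, the name rests on the 2 leading markers, HAND1 and KRT7. It does not set trophoblast apart from amnion. The other cluster of the APA-positive plate held most of its wells and the undifferentiated wells P23 and P24, and stayed unnamed, with immunoglobulin and hemoglobin genes such as IGLC2 and HBZ in the lead. This unnamed cluster also had 10 trophoblast markers detected, but none in the lead. Its median was 2793 UMIs, so the 2 clusters differed in depth as well. In the clustering without P23 and P24 it was led by the hemoglobin gene HBG1, LGALS1, TFF1, DLK1 and PUS7L. IGLC2 and HBZ were no longer among its 10 leading genes. The immunoglobulin gene IGLC3, the liver genes APOA2 and AFP, and DCT were among them, so such transcripts still led this cluster. There its summed level of trophectoderm and network genes was 4560 CPM, against 6960 CPM in the trophoblast-like cluster. The remaining 2 clusters, of undifferentiated wells almost alone, also stayed unnamed, since no marker was among their leading genes, though 8 pluripotent markers were detected in each. They were led by RNF8, USP44 and CUZD1, and by MGC32805, POU5F1B and TDGF1P3. No cluster had 2 or more mesoderm, endoderm or neuroectoderm markers among its leading genes.

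Of the APA-positive wells 9 (2.36%, 1.09 to 4.44) lay in clusters of the undifferentiated plate. All 9 stood opposite an undifferentiated well of at least 10000 UMIs, as did 27.6% of kept APA-positive wells. Of the APA-positive wells opposite no such well, none lay with the undifferentiated plate, which allows up to 1.09%. Clustering the APA-positive plate alone set apart a larger group of 57 wells, with MIR302CHG, TDGF1 and LINC00678 among its leading genes. Its pluripotency list stood at 5107 CPM, against 2232 and 2084 CPM in the other clusters of that plate. Of these 57 wells 56 lay opposite an undifferentiated well of at least 10000 UMIs. Pluripotency transcripts of shallow APA-positive wells (under 10000 UMIs) showed the same dependence on position. The list's summed level was 3859 CPM (3672 to 4053) opposite deep undifferentiated wells and 2266 CPM (2149 to 2389) opposite shallower ones. The pluripotency ratios over all kept wells include wells opposite deep ones. The deep-well subset leaves these out, but not wells opposite shallower ones.

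Genes that varied most between wells of 1 plate, by the Fano factor of thinned counts, were led on both plates by the kinase gene BRSK1 at 11.5 (APA-positive) and 8.94 (undifferentiated). Other leading genes of the APA-positive plate were the mitochondrial ribosomal RNAs MT-RNR2 (4.76) and MT-RNR1, the nuclear noncoding RNA MALAT1 (2.32), the cathepsin gene CTSV (1.63) and the X-linked deubiquitinase USP9X (1.59). On the undifferentiated plate MT-RNR2 (2.43), MALAT1 (1.51), MT-CO2 and mitochondrial pseudogenes followed. BRSK1 depended on plate position, with 1656 CPM (1544 to 1775) in rows I and O of the APA-positive plate against 187.1 CPM (172.2 to 203.1) in its other rows. On the undifferentiated plate it stood at 1527 CPM (1452 to 1604) in rows I and O against 273.4 CPM (257.2 to 290). Among deep-well subset wells of the APA-positive plate the leading genes were MALAT1 (30.4), SAT1, a polyamine-catabolic enzyme (29.1), MT-RNR2 (21.2), CTSV (11) and PEG10 (9.82), with IGFBP3 at 7.13. SAT1 had a mean of 2.67 UMIs per thinned well, with 62 in well L15 and 0 in 17 wells. Its value thus rests largely on 1 well, which also held the most MALAT1 UMIs.

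**Figure D4:**
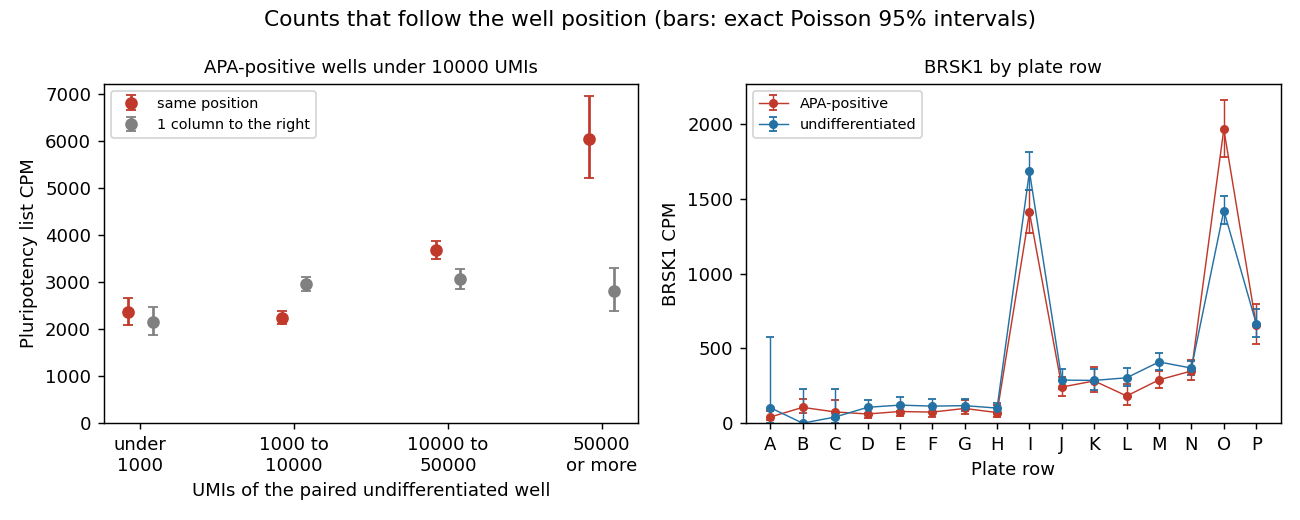
Plate position and 2 kinds of transcript, with the pluripotency list CPM of shallow APA-positive wells by the UMIs of the well at the same position of the undifferentiated plate, and BRSK1 CPM by plate row for both plates (bars show exact 95% intervals). The pluripotency list stands at 2266 CPM opposite wells under 10000 UMIs and at 3859 CPM opposite deeper ones, and BRSK1 is highest in rows I and O on both plates.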

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

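All marker lists and tests below were chosen after the leading genes of wells P23 and P24 had been seen, the correlation test after the Fano factor, and the test of an even addition and the fractions by depth after the other values.

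Wells P23 and P24 drew attention because they held a signal outside the comparison of the 2 cell states, in wells the labels do not set apart. Their liver marker genes (ALB, AFP, APOA1, APOA2, APOB, FGA, FGB and SERPINA1) summed to 2782 CPM on the APA-positive plate and 2687 CPM on the undifferentiated plate. The other kept wells stood at 750 and 630 CPM (27% and 23.4% of that level). AFP, APOA1 and APOA2 are also in the endoderm list. Markers of red blood cells stood in the other wells at 22% and 17.4% of their level in P23 and P24, of plasma cells at 13% and 10.5%, and of melanocytes at 28.9% and 26.8%.

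A candidate explanation is that P23 and P24 held RNA mixed from several cell types, as reference samples do, and that some of it or its reads spread over the plates. The liver list was 1.87 times higher in CPM in wells under 3000 UMIs than in deep wells on the undifferentiated plate, and 2.85 times on the APA-positive plate. The same number of UMIs added to every well is argued against by the liver UMIs per well. On the APA-positive plate deep wells held 5.43 times those of wells under 3000 UMIs, with 15.5 times the total UMIs. On the undifferentiated plate they held 12.7 times, with 23.9 times the total UMIs. Over all other kept wells the fractions of the 4 lists were at most 2.55 times apart, but 3.48 times in undifferentiated wells under 3000 UMIs, past the limit of 3 set for 1 source, which stays open.

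Sorted cells that made liver transcripts were set against such a spread. Liver UMIs did vary more between deep wells than chance gives, with a Fano factor of 4.34, which met the prediction for such cells. An addition that differs between wells raises the Fano factor too, so that value does not decide, and another test was run. Liver UMIs rose with the UMIs of the other 3 lists over deep wells, with r = 0.663 (rho = 0.484) on the undifferentiated plate and 0.704 (0.456) on the APA-positive plate, which argues against cells making liver transcripts alone as the whole cause. Whether a few cells made them too stays open. What the wells held and by which route their transcripts spread was not tested, and no biological explanation beyond liver-making cells was tested.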

How the results depend on the processing

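The settings were the 12 fixed before the data were examined and 3 chosen after (without P23 and P24, deep wells, and the deep-well subset), with 4 more of the former kind for list counts. Of 120 named genes 82 were at least 2-fold apart, and 81 of these kept their direction under every setting that gave a value. HLA-B did not, with a log2 ratio of 1.05 that became −0.41 in plate columns 1 to 12, −0.40 in deep wells and −1.36 in the deep-well subset, and the cause was not tested. Many of the 82 genes were named for large ratios in these same data, so a kept direction is a weak check. With every well thinned before summing, the pluripotency members at least 2-fold lower went from 19 of 24 to 12 of 17 measured, and the amnion members at least 2-fold higher from 11 of 13 to 7 of 9, because fewer members were measured. All other counts of the network, pluripotency, trophectoderm and amnion lists in their main direction stayed within 1.5 times. The TMM factor moved none of the 120 gene ratios beyond its counting interval, nor did leaving out the cell filter or a stricter one. Leaving mitochondrial genes out of totals moved 3. Thinning before summing moved 76, no wells of high UMI count 71, and no wells that clustered with the other plate 62. The mean of each well's own CPM moved 56. Plate rows A to H moved 70 and rows I to P 44. Plate columns 1 to 12 moved 65 and columns 13 to 24 moved 37. Without P23 and P24 49 moved, in deep wells 67 and in the deep-well subset 90. The reversals of HLA-B are not in these counts, and a few genes had no value under some settings. Without P23 and P24 the basement membrane and matrix members at least 2-fold lower went from 1 to 5 of 11. Of the Nodal and Activin list 4 of 10 members were measured, of neuroectoderm 6 of 14 and of differentiated trophoblast 13 of 26, and whether depth or absent expression set this was not tested. No paired analysis was possible because each group is 1 plate, the shared numbers only name wells, and no test was run.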

Other observations

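Of the tests below, those of carry-over at the same position, of cells that stayed undifferentiated, of BRSK1 by row and by shared position, of pairs of differentiated trophoblast genes, and of the clusters without the 11 wells were chosen after the result was seen. The deep-well subset and its clusters were also chosen after seeing the data.

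The deep-well subset of the APA-positive plate fell into 2 clusters. One of 11 wells was led by ERVFRD-1, CGA, NLRP2, GREM2, HSPB8, PGF, GCM1 and OVOL1, several of which mark trophoblast on its way to syncytium, and held GATA2 at 813 CPM (723 to 912). The other of 38 wells was led by LINC01405, MEIS1, ISL1 and ACTC1, with GATA2 at 164.01 CPM (142.5 to 187.9) and VTCN1 at 130 CPM against 38.6 CPM. TFAP2A went the other way from GATA2, at 118.6 CPM in the 11 wells and 234.98 CPM (209.1 to 263.2) in the 38. GATA3 stood at 780 and 578 CPM, and ENPEP at 104.8 and 119.1 CPM. The amnion list as a whole stood at 1244 CPM (1131 to 1364) in the 11 wells and 1494 CPM (1428 to 1563) in the 38. The G2 and M phase list was lower in the 11 wells, at 3425 against 5267 CPM. Since the leading genes define the clusters, these levels describe them and are not a test. After thinning, CGA was detected in 6 of the subset's 49 wells, GCM1 in 8 and PGF in 7. CGA and GCM1 were found together in 1 well, CGA and PGF in 2, and GCM1 and PGF in 2. The summed levels therefore do not show that the 11 wells share these genes. Over how many wells the ERVFRD-1 UMIs were spread was not tested.

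A hypothesis is that the sorted cells may hold a small set that had gone further towards syncytiotrophoblast, with high GATA2. Over pairs of differentiated trophoblast genes, wells with both numbered 1.13 times the product of the shares (0.808 to 1.54), which leaves the question open, and pairs of 1 trophoblast and 1 amnion gene numbered 0.936 times. The value of 1.13 was under the bound of 1.2 set for no such cells, but its interval ran past the 1.5 set for them, and it was read as open once the interval was computed. The interval treats the pairs as independent, although they share genes and wells, so it may be too narrow. Clusters made without the differentiated trophoblast, amnion and network lists, of 40 and 9 wells, differed 3.10-fold in the differentiated trophoblast list, at 295.7 against 95.3 CPM. But the amnion list differed the same way, at 1556.5 against 723 CPM, so they do not set trophoblast against amnion genes. GATA2 stood at 352.2 CPM (321.8 to 384.7) in the 40 wells and 43.3 CPM (20.8 to 79.6) in the 9, so here the smaller group held the lower level. Whether GATA2 was high in a small set alone or rose by degrees was not tested. All 11 wells lay in the group of 40, which holds most of the subset's wells. In the differentiated trophoblast list the other 29 wells of that group stood at 140.8 CPM, 1.477-fold over the 9 (0.940 to 2.43). Members of this list led the cluster of 11, so leaving those wells out had to lower the level, and this value does not decide. The hypothesis stays open.

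Pluripotency transcripts on the APA-positive plate may in part be counts carried over from the same position of the other plate, as would happen if both used the same well barcodes, which the labels do not settle. Opposite deep undifferentiated wells the pluripotency list was 1.70 times higher in shallow APA-positive wells. Taking the well 1 column to the right as the partner gave 1.06, against a depth pattern shared by the plates. Of the APA-positive wells that clustered with the undifferentiated plate, 9 of 9 (8 of 9 without P23 and P24) lay opposite a deep undifferentiated well, against 27.6% of kept wells, which cells that stayed undifferentiated would not do. A fit over 300 wells put the carried part at 7.95% of the partner's pluripotency UMIs, which gives a ratio of 1.71 with the fitted own level of 15.9 UMIs per 10000, but simulated carry-over of 10% on the plate's mean level gave only 1.26, so the amount is uncertain. In the other direction no excess beyond counting error was seen. Trophectoderm and network transcripts of shallow undifferentiated wells stood at 1124 CPM (983 to 1280) opposite deep APA-positive wells. Opposite shallower ones they stood at 1068 CPM (1001 to 1137), a ratio of 1.05. Shared well barcodes would allow carry-over both ways, so this value does not go with an even exchange between the plates. Whether carry-over ran mainly from the undifferentiated plate was not tested.

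BRSK1 counts may be tied to the barcoded primers of certain wells. Rows I and O stood 5.58 times above the other rows on the undifferentiated plate and 8.85 times on the APA-positive plate. Carry-over alone is set against by the APA-positive wells deeper than their opposite well, where rows I and O (6 wells) still stood 14.1 times higher. Of the positions in the top quartile of BRSK1 on the APA-positive plate 55.7% (44.7 to 66.3) were so on the other plate, where chance gives 25.1%, which goes against cells that differ in BRSK1. The barcode sequences were not analysed here, so the cause stays open.

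Other genes followed position on both plates. RNF8 stood at 130.6 CPM in even and 28.5 CPM in odd columns of the APA-positive plate, and at 208.9 and 62.5 CPM on the undifferentiated plate. LINC02227 stood at 213.99 CPM in rows K and L against 13.2 CPM in rows A to H of the APA-positive plate, and at 170 against 20 CPM on the other.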
